A study of Homo sapiens with 4 samples.

How the data were processed

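The 4 libraries were analysed, 1 each from shNS and shDIS3L2 whole cells and from the EVs of each line. Per the labels' protocols, cells received 1 µg/mL doxycycline for 4 days and then 100 nM PMA for 24 h, and then medium depleted of EVs for 24 h, from which the EVs were collected. EVs were pelleted, floated in a sucrose gradient and treated with micrococcal nuclease. Per the labels' protocols, 50 ng of RNA entered each library, a 12-nt random sequence was added for deduplication and 15 amplification cycles were run. Cell RNA was depleted of ribosomal RNA. The EVs came from the medium of the same flasks as the cells, so the compartments are not independent cultures.

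The authors deposited 1 table of estimated counts for the 4 libraries, with 66845 rows. Per the submitters' processing notes, cutadapt, Salmon, UMI-tools and Novoalign and the builds hg38 and GRCm38 were used. Their roles, order, versions and annotation, and whether the counts are deduplicated, are not given in the sources used here. The values were not whole for 50.1% of the nonzero entries and were rounded to whole numbers. If several reads per molecule remain, counting intervals are too narrow, and they cover counting error only in any case.

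The rows held 65554 Ensembl transcript identifiers, 268 tRNA rows and 1023 repeat rows. 37 names stood on more than 1 row and were summed, leaving 66800 features. None of the transcript identifiers was paired with a symbol by the table or by the reference tables used (0 matched), so transcripts are not named. The 23 gene lists fixed before the data were examined matched 0 rows, so no list median was computed, and the level of DIS3L2 was not analysed here. For the same reason the knockdown could not be checked from these values and ribosomal RNA could not be removed before EVs were set against cells. The tRNA rows were summed into 49 anticodon families and the repeats into classes by name, groupings made after the row names were seen.

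Scaling factors were TMM effective library sizes (edgeR 4.0.16, R 4.3.3) for each pair of libraries. Ratios carry exact Clopper-Pearson conditional binomial intervals (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, Python 3.11.15). Figures were drawn with matplotlib 3.10.9. A feature was measured with 20 or more counts over the pair. The double ratio used TMM over the 4 libraries, a prior count of 0.5 and the Poisson variance of the log counts, for features with 20 or more counts in each compartment. Ratios of single features against 0 were computed against a floor of 3 counts in that library. Medians over repeat families and over random lists added 0.5 to each count, and medians at the floor are named as such.

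Named features followed a rule fixed before the data were examined: the 8 highest and 8 lowest by the interval bound nearest to 1, among features with 100 or more counts over the pair, and 5 each for the double ratio. As the transcripts carry no gene names, the rule was also applied to the tRNA and repeat features alone, anticodon families and repeat classes were described, and at most 2 higher and 2 lower transcript identifiers are printed. These adaptations were made after the data were seen. Rows of near-identical tRNA genes and of related repeat consensus sequences share reads and are uncertain.

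The calling step was tested on simulated Poisson counts with 200 changed features. In the cell comparison it recovered 100% of the 3-fold and of the 6-fold changes among 848 features. It recovered 84.6% of the 3-fold and 99% of the 6-fold changes between the EV libraries, among 2993 features. For EVs against cells it recovered 88.5% and 100% of the 3-fold and 6-fold changes in shNS (1396 features) and 91.4% and 99% in shDIS3L2 (2838 features), and for the double ratio 99% of the 6-fold changes (520 features). Of unchanged features, 0.769% were called in cells, 1.75% between EVs, and 1.16% and 1.85% for EVs against cells in shNS and shDIS3L2. The simulated counts held counting error only, so none of these rates covers further spread between real libraries. Alternatives planned before the data were examined were total counts, DESeq2 1.42.0 size factors, other count minimums, other fold limits and a 99% interval. TMM from tRNA rows, 20 counts in each library, tRNA rows summed per anticodon and thinning of the deeper EV library were added afterwards. TMM from protein-coding genes, sums of small-RNA families, class shares without ribosomal or mitochondrial RNA, and the alternatives for DIS3L2 and for gene lists were not run, since they need gene names.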

Results

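RNA was profiled in THP1, a human monocytic leukaemia cell line, after differentiation into macrophage-like cells with the phorbol ester PMA. The cells carried a doxycycline-induced short hairpin RNA, either a non-silencing control (shNS) or a hairpin against DIS3L2 (shDIS3L2), an exoribonuclease that degrades RNAs bearing untemplated uridine tails. RNA was taken from whole cells and from extracellular vesicles (EVs), small membrane-bound particles collected from the medium of the same flasks. Libraries were made with a thermostable group II intron reverse transcriptase, an enzyme that reads through structured RNAs such as tRNA. Each of the 4 groups had 1 library, so no knockdown difference has a replicate check. EVs were set against cells in 2 lines, which differ in the hairpin. No p-value is given, and intervals in brackets are 95% intervals of counting error only. The estimated counts summed to 53374215 in shNS cells, 60579713 in shDIS3L2 cells, 9261642 in shNS EVs and 21590850 in shDIS3L2 EVs. A value is called higher or lower when it differed by 2-fold or more and the counting interval excluded 1.

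Rows named as tRNA made up most of the EV libraries. Their share of counts was 48.6% in shNS cells, 53.5% in shDIS3L2 cells, 80.5% in shNS EVs and 84.9% in shDIS3L2 EVs. Each share had an exact Clopper-Pearson interval narrower than 0.1 percentage points. Any tRNA among the Ensembl transcripts, which carry no gene names here, is counted there and not in this share. After TMM scaling the tRNA sum was not higher in EVs than in cells, at 0.611-fold in shNS and 0.465-fold in shDIS3L2. By total counts its log2 ratios were 0.73 and 0.67. The initiator methionine tRNA, tRNA-iMet-CAT-1-1, was the most abundant tRNA row in every library. Ensembl transcripts took 51.4% and 46.5% of the counts of the shNS and shDIS3L2 cells, and 19.4% and 14.9% of those of the EVs. Repeat families, which are consensus sequences of transposable elements, took 0.000854% of the shNS cell counts (456 counts), 0.00392% of the shDIS3L2 cell counts (2377), 0.127% of the shNS EV counts (11733) and 0.178% of the shDIS3L2 EV counts (38416). Whole-cell RNA was depleted of ribosomal RNA and EV RNA, as the protocol is written, was not, so shares in cells and EVs have different starting material.

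**Figure D1:**
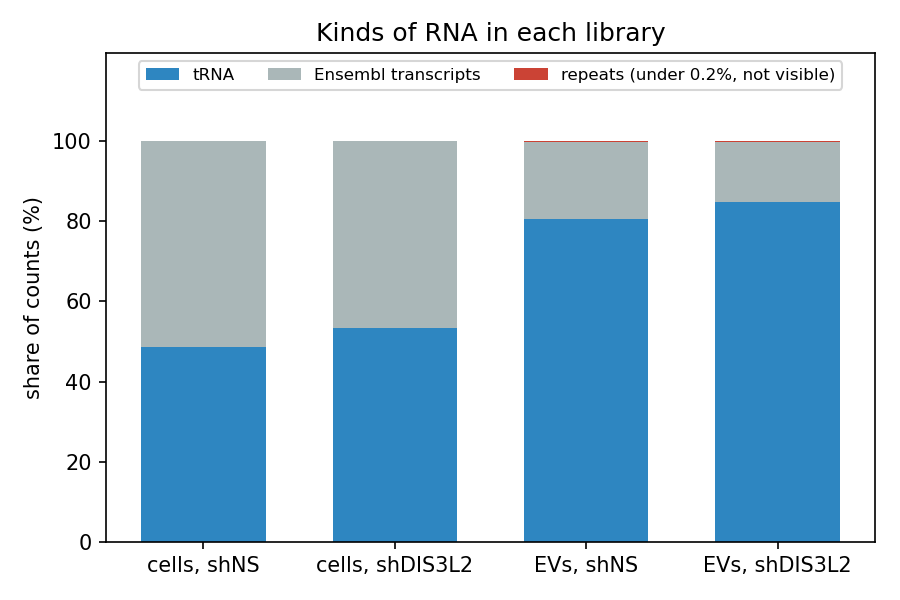
Stacked bars give the percentage of each library's counts that fell on rows named as tRNA, Ensembl transcripts and repeats, for the 4 libraries. The tRNA share is 48.6% and 53.5% in the cell libraries and 80.5% and 84.9% in the EV libraries.

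The first comparison asked how the RNA of the cells differed after DIS3L2 knockdown. The selenocysteine tRNA, which inserts selenocysteine at recoded stop codons, stood at 0.510-fold in shDIS3L2 cells [0.509 to 0.512], from 1002559 to 636077 counts. It was the lowest of the 48 measured anticodon families. It lay just short of 2-fold under the TMM scaling, and passed 2-fold when TMM was computed from tRNA rows alone (log2 ratio −1.02). Among the other families, glutamate tRNA with anticodon TTC was at 1.53-fold [1.52 to 1.54], aspartate tRNA (GTC) at 1.27-fold and serine tRNA (GCT) at 0.716-fold. No family reached 2-fold in either direction, and the log2 ratios of the 48 families had a standard deviation of 0.24 across families. The initiator methionine family was at 1.00-fold.

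Repeat reads were more frequent in the shDIS3L2 cells. The endogenous retrovirus HERV49I had 103 counts in shNS cells and 1479 in shDIS3L2 cells, an 11.6-fold difference [9.46 to 14.2]. With 1 culture per line, a difference between the cultures and the knockdown cannot be told apart for it. All other repeats summed were 2.05-fold higher [1.81 to 2.32], from 353 to 898 counts. L1 elements, the autonomous retrotransposons of the LINE group, were 3.54-fold higher [2.67 to 4.75] on 61 and 268 counts. Only 3 L1 families were measured, and they did not stand out from random lists matched on abundance. Their median log2 ratio was 1.83 against 1.03, at percentile 69.42. Alu elements, short retrotransposons derived from 7SL RNA, were at 0.820-fold with an interval that reached 1.00. AluYd3 was 2.66-fold lower, on 77 and 36 counts. These directions held under each scaling that was tried.

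Over all features, 93 were higher and 103 lower of 848 measured in cells. The tRNA rows gave 9 higher and 12 lower of 225, the transcripts 77 and 88 of 609, and the repeats 7 and 3 of 14. With a minimum of 100 counts over the pair, 23 were higher and 50 lower of 624. Several single tRNA rows passed 2-fold, among them tRNA-Glu-TTC-4-1, 2.15-fold higher [1.94 to 2.40], and tRNA-Leu-AAG-1-1, 4.19-fold lower, which went from 607 to 180 counts. Rows of near-identical tRNA genes share reads, so single rows are uncertain. Anticodon sums pool such rows within a family, and sharing of reads between families was not tested. A pair of transcripts without a gene name stands for the transcript rows. Transcript ENST00000580533 had 1411 and 21194 counts, 12.1-fold higher [11.5 to 12.8]. Transcript ENST00000692454 had 1369 counts in shNS cells and 0 in shDIS3L2 cells, 567-fold lower against a floor of 3 counts. The bound of its counting interval nearest to 1 was 461-fold. Each of these transcripts had 0 counts in both EV libraries.

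The second comparison asked how EV RNA differed after knockdown. The selenocysteine tRNA was at 0.541-fold (95% counting interval 0.539 to 0.544), short of 2-fold under each scaling. Leucine tRNA with anticodon TAA was at 1.87-fold [1.85 to 1.90], glutamate tRNA (CTC) at 1.45-fold and aspartate tRNA (GTC) at 1.38-fold, all under 2-fold. One family was lower by the 2-fold rule: serine tRNA with anticodon AGA had 548 counts in shNS EVs and 98 in shDIS3L2 EVs, a log2 ratio of −3.73. That difference rested on 1 row, tRNA-Ser-AGA-2-1, with 511 counts against 0, while the same row had 1295 and 1420 counts in the cells. No family was higher. Across the 47 families with 100 or more counts in each library, the knockdown ratios in cells and in EVs had a Pearson r of 0.591 and a Spearman rho of 0.412, and r was 0.442 without the selenocysteine tRNA. The 100-count limit left out serine tRNA (AGA), and with it r was 0.405 and rho 0.440 across 48 families. These correlations are across genes, which are not independent replicates.

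**Figure D2:**
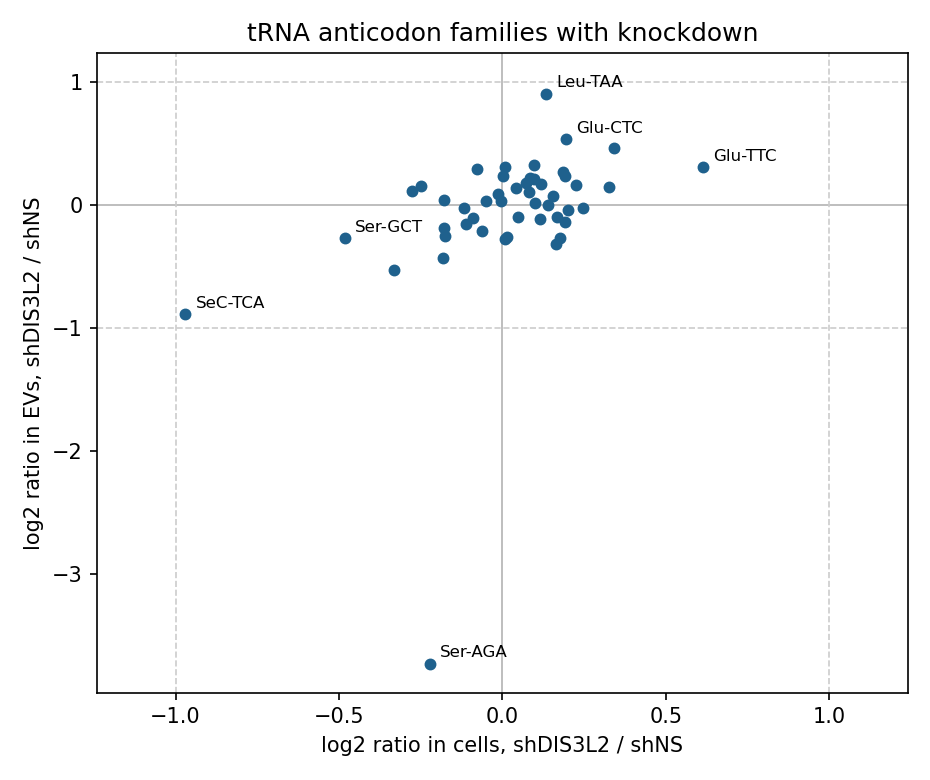
Each point is a tRNA anticodon family with 20 or more counts in all 4 libraries, placed by its log2 shDIS3L2 to shNS ratio in cells (horizontal) and in EVs (vertical), after TMM scaling of each pair. Dashed lines mark 2-fold. The selenocysteine family (SeC-TCA) lies at −0.97 and −0.89, and Ser-AGA at −3.73 on the EV axis.

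HERV49I was also higher in the shDIS3L2 EVs, with 112 and 2106 counts, 7.92-fold [6.55 to 9.66]. The other repeats together were at 1.32-fold [1.29 to 1.34]. Summed by class, long terminal repeat and retrovirus sequences, HERV49I included, were at 1.92-fold, L1 elements at 1.17-fold, and Alu elements at 1.06-fold with an interval that held 1. Counted by family, 76 long terminal repeat families were higher and 20 lower of 124, 33 L1 families higher and 8 lower of 74 and 15 Alu families higher and 2 lower of 19, where 56.9% of all features were higher. With 0 counts at the floor of 3, their median log2 ratios were 1.69, 0.94 and 2.49. With 0.5 added to each count the medians were 2.04, 0.91 and 5.09, against 0.97, 0.32 and 4.59 for matched random lists (percentiles 99.91, 99.45 and 93.51), and the median of all features was 2.25. The other classes lay at percentiles of 47.04 (SVA), 69.38 (other repeats), 71.16 (MER) and 78.29 (DNA transposons). L1HS, the youngest human L1 family, was at 0.972-fold on 974 and 2248 counts. MER41A, a long terminal repeat, had 171 counts in shDIS3L2 EVs and 0 in shNS EVs, 24.0-fold higher against the floor. The lower bound of its counting interval was 19.3-fold. LTR17 was 24.0-fold lower, on 91 and 9 counts.

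Over all features, 1721 were higher and 577 lower of 3025 measured in EVs. Of the higher features 1268 had 0 counts in the shNS EV library, and of the lower 236 had 0 counts in the shDIS3L2 library. The excess of higher calls was smaller at equal depth: with the shDIS3L2 EV library thinned to the depth of the shNS one, a setting chosen after the data were seen, 685 were higher and 540 lower. With a minimum of 100 counts over the pair at full depth, 182 were higher and 70 lower of 624. A minimum on the sum still favours features of the deeper library, so it does not separate the excess from depth. The excess turned with 20 or more counts required in each library, where 72 were higher and 119 lower. That filter, also chosen afterwards, drops every feature absent from 1 library. Whether features present in 1 EV library only reflect the knockdown, the preparations or several reads per molecule is left open. Among abundant transcripts, ENST00000648200, the most abundant transcript row of both EV libraries and chosen after its values were seen, was 2.50-fold lower in shDIS3L2 EVs, at 502173 and 477651 counts. ENST00000387342 was 8.97-fold higher [8.64 to 9.32] in shDIS3L2 EVs, with 2788 and 59393 counts, and at 0.650-fold in shDIS3L2 cells, a contrast that 1 library per group cannot assign to the knockdown.

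The third comparison set EVs against cells within the control line. Lysine tRNA with anticodon TTT was 6.68-fold higher in shNS EVs than in shNS cells after TMM scaling. Its most abundant row, tRNA-Lys-TTT-3-1, was 6.69-fold higher [6.60 to 6.79] on 81492 and 25913 counts. Serine tRNA (TGA) was 2.72-fold higher, alanine tRNA (AGC) 2.49-fold, glycine tRNA (GCC) 2.42-fold, serine tRNA (GCT) 2.37-fold and valine tRNA (TAC) 2.13-fold. The families lowest in EVs were arginine tRNA (CCG) at 0.193-fold, leucine tRNA (TAA) at 0.263-fold, the initiator methionine tRNA at 0.301-fold and leucine tRNA (TAG) at 0.304-fold. In all, 6 families were higher and 8 lower of 48. The order of the families does not depend on scaling, but their direction does: scaling by total counts moved every log2 ratio up by 1.44, and then 30 families were higher and 0 lower, with aspartate tRNA (GTC) changing from −1.24 to 0.20.

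Repeats were higher in EVs under every scaling tried. L1 elements were 222-fold higher in shNS EVs than in shNS cells [172 to 290], on 6356 and 61 counts. Long terminal repeat sequences, HERV49I included, were 40.6-fold higher [34.4 to 48.3] and Alu elements 8.96-fold [7.69 to 10.5]. HERV49I, itself 2.31-fold higher, held 103 of the 148 long terminal repeat counts in shNS cells. Of 114 measured repeat families 111 were higher, including all 39 L1 families, and 81 of the 111 had 0 counts in cells. L1HS had 974 counts in EVs and 10 in cells, a 207-fold difference [112 to 434]. The median log2 ratio of the L1 families was 7.36, or 5.00 with 0 counts replaced by the floor of 3, and lay at percentile 100.00 of 10000 random lists matched on abundance (median 6.47). In this line the other repeat classes did not stand out from matched lists, with percentiles of 31.33 (MER), 64.30 (Alu), 74.86 (DNA transposons), 74.89 (long terminal repeats) and 79.79 (SVA). Transcripts as a sum were 7.17-fold lower in EVs after TMM scaling, and their log2 ratio by total counts was −1.40. Of 112 transcripts with 10000 or more counts in both cell libraries, 98 were at least 8-fold lower. That set was chosen for high cell counts, the denominator of the ratio, which favours lower values. Of all measured transcripts 41.9% were lower and 55.7% higher. Over all features, 740 were higher and 514 lower of 1392. With a minimum of 100 counts, 110 were higher and 420 lower.

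In the knockdown line the EV to cell ratios of the tRNA families were in nearly the same order, with a Pearson r of 0.970 and a Spearman rho of 0.964 across 47 families. Serine tRNA (AGA), left out there by the 100-count limit, was the exception, with log2 ratios of −0.24 in shNS and −4.19 in shDIS3L2, and with it r was 0.846 and rho 0.943. Lysine tRNA (TTT) was again the highest, at 4.86-fold, followed by serine tRNA (TGA) at 2.15-fold and serine tRNA (GCT) at 2.02-fold. Arginine tRNA (CCG) was at 0.184-fold and serine tRNA (AGA) at 0.0549-fold. By the 2-fold rule 3 families were higher and 16 lower, and 7 and 6 with TMM from tRNA rows. Scaling by total counts moved the log2 ratios up by 1.77 and gave 24 higher and 1 lower, while DESeq2 size factors moved them by −0.62. L1 elements were 54.1-fold higher in EVs [48.0 to 61.3] and long terminal repeat sequences, HERV49I included, 6.19-fold [5.89 to 6.52]. HERV49I held 1479 of the 1705 long terminal repeat counts in shDIS3L2 cells. The class ratio therefore leans on that row and is not a measure of the class as a whole. Of 271 repeat families 267 were higher. Against matched random lists the L1 families lay at percentile 100.00 (median log2 ratio 5.78 against 4.44) and the long terminal repeat families at 99.95 (5.59 against 5.21), which was 74.89 in the shNS line. With 0 counts at the floor these medians were 4.60 and 4.00. The other classes lay at 43.24 (Alu), 61.39 (DNA transposons), 75.09 (other repeats), 80.88 (SVA) and 90.09 (MER). HERV49I was at 1.17-fold, and below 1 with DESeq2 size factors (log2 ratio −0.39). Over all features, 2104 were higher and 554 lower of 2843, and with a minimum of 100 counts 254 were higher and 448 lower. Of 1001 features measured in both lines, 346 were higher in EVs in both, 464 lower in both and 16 opposite, against 138, 245 and 368 for independent lists.

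**Figure D3:**
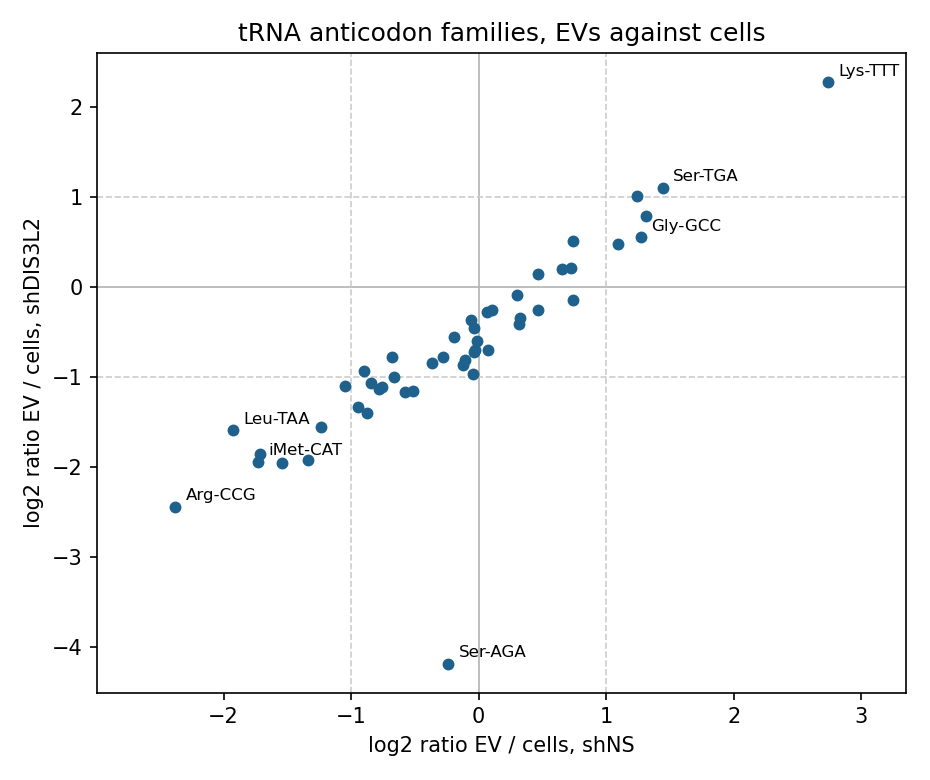
Each point is a tRNA anticodon family with 20 or more counts in all 4 libraries, placed by its log2 EV to cell ratio in the shNS line (horizontal) and in the shDIS3L2 line (vertical), after TMM scaling of each pair. Dashed lines mark 2-fold. Lys-TTT is highest in both lines (2.74 and 2.28), and total-count scaling would shift the points by 1.44 and 1.77 without changing their order.

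The last comparison asked whether knockdown altered the EV to cell ratio. The median double ratio of the 520 features measured in both compartments was −0.41 on the log2 scale, a shift set by the scaling over 4 libraries, so values are best read against it. The selenocysteine tRNA was at −0.34, near that median, as its log2 ratios with knockdown were −0.97 in cells and −0.89 in EVs. Serine tRNA (AGA) was the lowest measured family, at −3.93, a value resting on the row tRNA-Ser-AGA-2-1. Leucine tRNA (TAA) was the highest, at 0.35. The order of the families does not depend on scaling, but which of them lie above 0 does. Among single rows, tRNA-Ile-AAT-3-1 was 16.3-fold higher [8.04 to 33.0], on 65 and 59 counts in cells and 10 and 397 in EVs. The row tRNA-Lys-TTT-1-1 was 8.42-fold lower [6.35 to 11.2], on 113 and 102 counts in cells and 2128 and 584 in EVs. ENST00000387342 was 10.3-fold higher by the double ratio [9.91 to 10.7]. By the 2-fold rule 85 features were higher and 127 lower, a higher share of 40.1%. That split depended on scaling: the higher share was 51.4% with total counts and 55.4% with DESeq2 size factors or with TMM from tRNA rows.

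**Figure D4:**
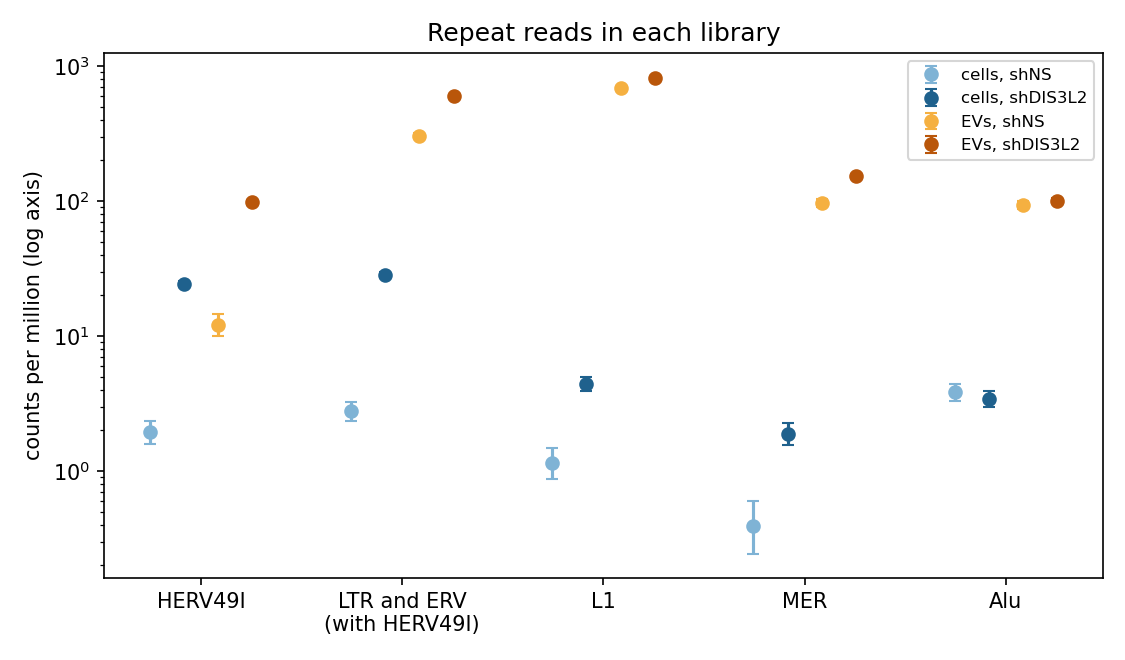
Points give CPM, on a log axis, of HERV49I and of the long terminal repeat and retrovirus (ERV, with HERV49I), L1, MER and Alu groups in each of the 4 libraries. Bars are exact 95% counting intervals. L1 elements stand at 1.14 and 4.42 CPM in cells and 686 and 818 in EVs, and HERV49I at 1.93 and 24.4 in cells and 12.1 and 97.5 in EVs.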

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

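No paired analysis was possible for the knockdown because each group had 1 library. EVs and cells of a line form a pair, and with 2 such pairs the calls of both lines were set side by side and not tested. Total-count, DESeq2 and tRNA-only scaling and the 99% interval kept each count of higher and lower features within 1.5 times its main value, as did summing tRNA rows. 73 of 106 alternative counts did so, and the cause of the others was not tested beyond what each setting removes. In the lists that follow, higher and then lower counts are given. With no minimum above 1 count they were 312 and 267 in cells with knockdown, 2620 and 1273 in EVs with knockdown, 3810 and 854 for EVs against cells in shDIS3L2, and 190 and 313 for the double ratio, and higher features in shNS EVs against cells were 1906. With a minimum of 100 counts they were 23 and 50, 182 and 70, and 34 and 54 for cells, EVs and the double ratio, and for EVs against cells 110 and 420 in shNS and 254 and 448 in shDIS3L2, where the larger side turned from higher to lower. With 20 or more counts in each library, a setting chosen after the data were seen that also removes features absent from 1 library, they were 17 and 53 in cells, 72 and 119 in EVs, 64 and 176 for EVs against cells in shNS, 57 and 245 in shDIS3L2, and 28 and 62 for the double ratio, so the larger side turned from higher to lower in EVs and in both lines' EVs against cells. The 4-fold rule gave 61 and 37 in cells and 72 lower double ratios, and the 1.5-fold rule 207 lower double ratios. Thinning the shDIS3L2 EV library, also chosen afterwards, left 685 higher with knockdown in EVs and 881 higher in shDIS3L2 EVs against cells. Total counts turned the log2 ratios of EVs against cells of 3 of 14 called tRNA families in shNS and 10 of 19 in shDIS3L2, all from lower to above 0 and by a shift common to all features. They included the selenocysteine tRNA (0.66 in shDIS3L2), aspartate tRNA GTC (0.20 in shNS and 0.22 in shDIS3L2) and leucine tRNA TAA (0.18 in shDIS3L2). The settings that need gene names, such as TMM from protein-coding genes, were not run. Depth limits scarce EV features most: the shNS EV library has 9261642 counts, so a floor of 3 counts is 0.324 CPM.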

Other observations

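All tests in this part were chosen after the results they measure had been seen.

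The knockdown differences of cells and EVs went the same way more often than opposite ways. Of 520 features measured in both compartments, 35 were called in the same direction, against 16.0 if the lists were independent, and 16 in opposite directions, against 14.3. By kind, the same and opposite directions numbered 7 and 1 for tRNA rows, against 0.976 each, 23 and 15 for transcripts, against 16.2 and 14.6, and 5 and 0 for repeats, against 3.58 and 1.08. The tRNA row with opposite directions, tRNA-Ala-AGC-12-1, had 20 and 89 counts in shNS and shDIS3L2 cells and 18 and 21 in the EVs. Across 47 tRNA families, cell abundance in 1 line was set against the EV to cell ratio in the other. With abundance in shDIS3L2, Spearman rho was −0.591 and Pearson r −0.471, and with abundance in shNS −0.586 and −0.444. With serine tRNA (AGA), which the 100-count limit left out, rho was −0.563 and −0.491 and r −0.422 and −0.140. Cell abundance is the ratio's denominator, and the families differed little between the cell libraries (standard deviation of log2 ratios 0.24). A negative correlation can therefore arise from the shared denominator alone, and its size without any relation was not computed. Whether families abundant in cells are scarcer in EVs cannot be decided from these values. These are correlations across genes.

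Many features had 20 or more counts in 1 EV library and 0 in the other, which counting error at these depths does not give: 236 of the 1020 features at 20 or more in shNS EVs were at 0 in shDIS3L2 EVs, where a Poisson model expects 2.86e-19. Greater depth of the shDIS3L2 library accounts for part of the imbalance and not for the pattern: 1268 features had 20 or more counts there and 0 in shNS EVs, and 366 did after thinning to equal depth, against 256 the other way. Thinning took the features with 20 or more counts from 2476 to 1149, close to the 1020 of shNS EVs, and the detected features from 6892 to 6082, against 3449. Several reads per original molecule may remain in the counts: of transcripts and repeats with under 100 counts, 41.1% and 51.7% had 10 or more in the EV libraries and 15.0% and 13.5% in cells. That explanation and a true difference between EV preparations cannot be told apart without reads per molecule. Transcripts made up 225 of the 236 features and 1162 of the 1268. Among features with 20 to 99 counts in shNS EVs, 36.5% of transcripts, 10.2% of repeats and 4.17% of 24 tRNA rows were at 0 in shDIS3L2 EVs. In the other direction these shares were 64.8%, 47.3% and 10.7% of 28 tRNA rows. Other explanations for this split between kinds of row were not tested.

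HERV49I was higher with knockdown in both compartments. An equal increase of all repeat reads was argued against as the whole cause, as the other repeats were 2.05-fold higher in cells against 11.6-fold for HERV49I. That comparator leans on Alu elements, with 204 of its 353 counts in shNS cells, while L1 elements were 3.54-fold higher. HERV49I was picked as the highest named feature in cells, so an increase that is uneven between families is not excluded. Scaling was argued against too, since the lowest log2 ratio in cells over the scalings was 3.48. A difference between the cultures other than the knockdown may account for it and cannot be told apart from the knockdown with 1 culture per line. In all, 3 features, HERV49I among them, were 5-fold higher in both compartments, of 314 with 100 or more counts in each pair, against 0.35 expected from independent lists. HERV49I had been picked for its high ratio, and the cells and EVs of a line came from the same flasks. This excess therefore does not separate the knockdown from the culture.

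Of the 98 abundant cell transcripts that were at least 8-fold lower in shNS EVs, 26 were higher in shDIS3L2 EVs and 12 lower. The 98 were picked for low shNS EV values, the denominator of this ratio, which by itself favours higher calls. Of all transcripts measured in EVs, 60.7% were higher and 20.4% lower. The 26 included 15 of 16 neighbouring abundant transcripts in the order of identifiers, and the 16 were at a median of 4.42-fold in shDIS3L2 EVs and at a median log2 ratio of −0.61 in shDIS3L2 cells. Carry-over of all cell RNA alike, in proportion to its level, predicts most of the 98 to be higher, and 26.5% were. Of the 82 outside the 16 neighbours, 11 were higher and 12 lower. Carry-over of only some cell RNAs into 1 EV preparation was not tested and is not excluded by these counts. Higher levels in cells were also argued against, since the 26 had a median log2 ratio of −0.43 there. Knockdown and a difference between single EV preparations could both give the pattern and cannot be told apart with 1 library per group, so a selective change in EV content is a hypothesis only.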
